A study of Mus musculus with 5 samples.

How the data were processed

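RNA from the cochlear sensory epithelium of mouse embryos at E13.5 was sequenced in 5 libraries, 3 from wild-type (WT) embryos and 2 from Trim71 knockout (KO) embryos; per the labels the controls were littermates and the epithelia were freed with enzymes. Doxycycline was given from embryonic day 8.5 for 5 days, per the labels. Libraries were made with a stranded total RNA kit and read as paired ends of 50 bases, per the labels' protocols. The labels do not say which exons of Trim71 are removed, or whether a library holds 1 embryo or several. P-values therefore measure only the spread between these libraries, part of which may be technical.

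The deposited values are estimated counts per transcript, which need not be whole, with each transcript's length and effective length. Per the submitters' processing notes the authors used kallisto, which assigns reads to transcripts without aligning them to the genome, and sleuth. Their versions, the kallisto index and the strand setting are not given in the sources used here. Each library listed 118489 transcripts, and 116728 of them matched transcripts of GENCODE release M21 (mouse build GRCm38) by identifier and version. The other 1761 transcripts held between 0.558% and 0.589% of the counts of a library and were tied to no gene.

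Estimated counts were summed over the transcripts of each gene and rounded to whole numbers. Library totals ranged from 45858261 to 52568356 estimated counts. At this depth a count of 0 allows up to 3 counts, and such limits cover counting error only, since reads without molecular identifiers are not independent molecules. Genes whose reads can be split with near-identical copies, pseudogenes among them, are uncertain. CPM values use TMM-scaled library sizes. TPM was not among the columns used from the deposited files and was computed from the estimated counts and effective lengths for 1 alternative.

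Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, the filterByExpr filter and a robust quasi-likelihood F test on genotype. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, with a threshold of 0.05. Standard errors were taken as the log2 fold change divided by the square root of the F statistic. Gene lists, 32 in all, were written before the data were examined. Of these, 31 were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, and the sex-linked list served only as a check. Camera with an estimated correlation and fry, a test of whether the genes of a list move on balance one way, were alternatives.

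The named genes follow a rule written before the data were examined. It takes Trim71 and 11 focus genes, whatever their result. It adds the 10 highest and 10 lowest log2 fold changes among genes past the threshold that had a mean of at least 1 CPM, a symbol that is not a predicted or clone name, and all KO libraries on one side of all WT libraries. Fewer than 10 genes qualified as lowest, so all 7 are named. Up to 4 members with the smallest p of each described list complete it. The result of 1 gene that the rule takes is not reported here. Genes on the Y chromosome are used only to check the embryos' sex, and the sex covariate rests on Ddx3y, Uty and Eif2s3y, without Kdm5d.

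The test was tried in 1 run on simulated counts with the real libraries' means, sizes and fitted dispersions, with 200 genes changed. Genes were drawn independently, so correlation between genes was left out. The filter kept 18523 of the simulated genes, and a changed gene that it removed would count as not recovered. The test recovered 28.4% of genes changed 1.5-fold, 50.7% of those changed 2-fold and 75.8% of those changed 4-fold for the KO and WT comparison. Of 120 calls, 17 were false, a larger share than the threshold of 0.05 aims for. The alternatives were another scaling, other filters, DESeq2 1.42.0, limma-voom, an effective-length offset, limma on log2(TPM + 1), a fit that is not robust, transcripts in place of genes, protein-coding genes only and each library left out. Covariates for sex, for the share of counts on protein-coding transcripts and for a mesenchyme score, autosomal genes only, and a count without members of the other-cell lists were chosen after seeing the data. Sleuth was not run here, and the deposited values held no bootstraps that were used.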

Results

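The series measured gene expression in the cochlear sensory epithelium, the part of the developing inner ear that forms hair cells and supporting cells, at embryonic day E13.5. The WT libraries, replicates 1, 2 and 3, held 46978580, 45930372 and 52568356 estimated counts. The Trim71 KO libraries, replicates 4 and 6, held 45858261 and 49135511. Transcripts of the Y chromosome were present in WT replicate 1 and in both KO libraries, with summed values of 256, 258 and 220 CPM for 4 Y-linked genes, and were lower in WT replicates 2 and 3, with 27.3 and 13.0 CPM, of which Kdm5d made up 21.8 and 10.7 CPM. The first principal component of log2 CPM held 39.1% of the variance and did not part the genotypes, with WT replicate 2 at 36.5 and KO replicate 4 at 34.4 on it and WT replicate 1 at -7.12 and KO replicate 6 at -10.6. The groups lay apart on the second, which held 27.7%.

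The study asks what loss of TRIM71, an RNA-binding protein, does to the timing of development in this epithelium. Trim71 itself (ENSMUSG00000079259.2, chromosome 9, 114507133 to 114564369, minus strand, GRCm38) was at 49.1 CPM ± 3.89 (SD, n = 3) in WT and 38.9 CPM ± 3.86 (SD, n = 2) in KO. Its log2 fold change was -0.34 ± 0.09 (SE), which did not pass the threshold in edgeR (adjusted p = 0.235). Both KO libraries, at 41.6 and 36.2 CPM, lay below the WT libraries at 49.3, 45.1 and 52.9 CPM. The removed exons are not given in the sources used here, and whether the counts in KO come from an altered transcript or from cells without the deletion was not tested, so this level does not check the labels.

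Among the 11 focus genes, Atoh1, the transcription factor that starts hair cell differentiation, rose in the KO libraries. It went from 0.329 CPM ± 0.154 (SD, n = 3) in WT to 3.97 CPM ± 1.34 (SD, n = 2) in KO, a log2 fold change of 3.59 ± 0.43 (SE; edgeR adjusted p = 0.0103). The counts behind it were 15, 23 and 9 in WT against 139 and 239 in KO. Pou4f3, a hair cell transcription factor that acts after Atoh1, had 1, 0 and 0 counts in WT against 10 and 13 in KO, and did not pass (edgeR adjusted p = 0.112). Without KO replicate 6 the log2 fold change of Atoh1 was 3.198 (edgeR adjusted p = 0.0843); here and below, a fit without a KO library has 1 KO library left, so its spread comes from the WT libraries alone. Atoh1 also did not pass with limma on log2(TPM + 1) (adjusted p = 0.191), where its log2 fold change was 1.8. Adding 1 to TPM shrinks fold changes at low levels. Nor did Atoh1 pass with sex (edgeR adjusted p = 0.0898) or the mesenchyme score (edgeR adjusted p = 0.869) as a covariate. Its log2 fold changes there were 3.615 and 2.951.

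The other focus genes did not pass the threshold either. Lin28a and Lin28b, RNA-binding proteins that block let-7 maturation, had log2 fold changes of -0.80 ± 0.38 and -0.48 ± 0.22 (SE). Hmga2 and Igf2bp1, which let-7 represses, had values of -0.27 ± 0.17 and -0.29 ± 0.10. Inhba, which encodes a subunit of activin, had a value of 0.66 ± 0.15 (edgeR adjusted p = 0.14). The cell cycle inhibitors Cdkn1a and Cdkn1b had values of -0.27 ± 0.08 and 0.30 ± 0.13. Sox2, a prosensory transcription factor, and Fgf20, a growth factor of the same domain, had values of -0.12 ± 0.13 and -0.10 ± 0.13.

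**Figure D1:**
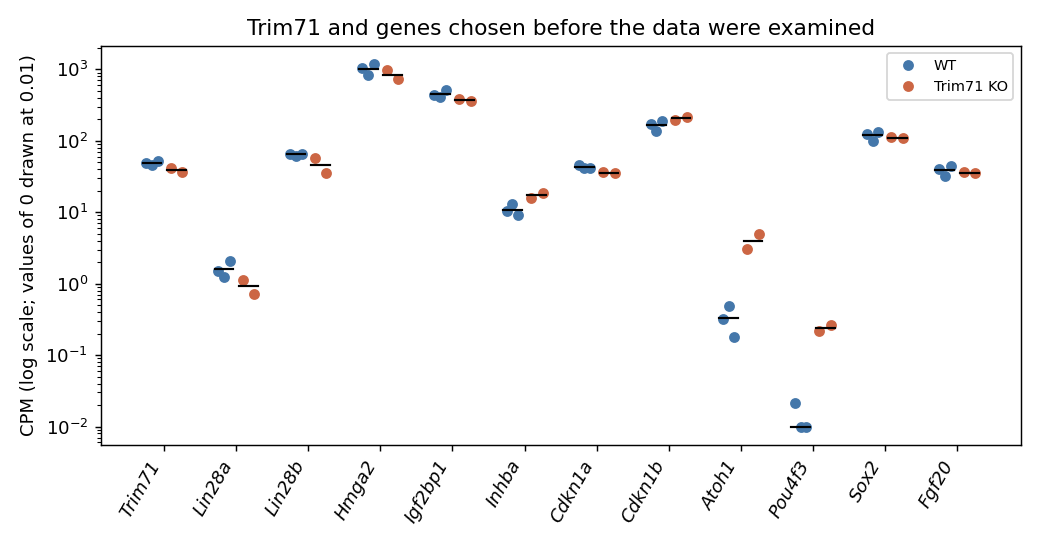
CPM per library on a log scale for Trim71 and the 11 focus genes, with 1 point per library (WT blue, Trim71 KO orange) and a bar at each group's mean; values under 0.01 are drawn at 0.01. Atoh1 is at 3.03 and 4.92 CPM in the KO libraries and at most 0.486 CPM in the WT libraries.

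The genes past the threshold were mostly higher in the KO libraries, while the median log2 fold change of all tested genes was -0.0057. Of 18862 tested genes, 104 passed the threshold in edgeR, 95 higher and 9 lower. The highest was Ccr4, a chemokine receptor gene that lies beside Trim71 on chromosome 9, which went from 0.348 CPM ± 0.138 (SD, n = 3) to 26.8 CPM ± 2.84 (SD, n = 2). Among the called genes that the naming rule takes, which have a mean of at least 1 CPM, pigment cell genes came next. Tyrp1, a melanin synthesis enzyme, had a log2 fold change of 6.15 ± 0.59 (SE), and Trpm1, a channel of melanocytes that is also in the supporting cell list, had 3.79 ± 0.41.

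The rest of the 10 highest by that rule were Atoh1, Mmp9, Olfml2a, Car3, Pde2a, Plac9b and Serpinb5. Mmp9, a secreted protease, rose with a log2 fold change of 3.15, and Olfml2a with 3.04. Car3, a carbonic anhydrase, rose by 2.83, and Pde2a, a phosphodiesterase, by 2.75 on that scale. Plac9b and Serpinb5 had values of 2.64 and 2.63. The genes that fell included Olig1, a transcription factor, with a log2 fold change of -1.63 ± 0.24 (SE), and Tacr3, a tachykinin receptor, with -0.94 ± 0.15. Zfp385c, Atp2b2, Samd5, Cemip and Lrig1 fell with values of -0.65, -0.59, -0.59, -0.57 and -0.39. Atp2b2 encodes a calcium pump of hair cells. Each of these 7 genes that fell lost its call in edgeR without WT replicate 1 and without KO replicate 6, with highest adjusted p from 0.18 for Atp2b2 and Samd5 to 0.409 for Lrig1; all but Atp2b2 lost it without KO replicate 4, and Tacr3, Zfp385c, Cemip and Lrig1 without WT replicate 3. Their log2 fold changes without KO replicate 6 lay between -1.695 and -0.376. Plac9b reached an edgeR adjusted p of 0.565 without KO replicate 6, at a log2 fold change of 1.632, and, of the fits without 1 library, passed only in that without KO replicate 4. Pde2a had an edgeR adjusted p of 0.0866 without KO replicate 6, at a log2 fold change of 2.673. With the effective-length offset its log2 fold change was 0.406 (edgeR adjusted p = 1), and limma on log2(TPM + 1) gave 0.241 (adjusted p = 0.999), so its rise depends on how transcript length is treated. Mmp9 had log2 fold changes of 3.153 without KO replicate 4 and 3.158 without KO replicate 6, with edgeR adjusted p of 0.062 and 0.105.

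All 104 called genes had both KO libraries on one side of the WT libraries, as did 3925 of all tested genes, where chance gives 20%. The 104 were called for such differences in these same libraries, so their separation is not separate evidence. The count was 374 without WT replicate 2 and 32 without KO replicate 6 in edgeR. Of the 23 named genes past the threshold, 7 passed in each of the 5 fits that left out 1 library, namely Ccr4, Tyrp1, Trpm1, Olfml2a, Car3, Serpinb5 and Epyc. Of the same 23, these 7 and Atoh1 passed with the effective-length offset, and Ccr4, Tyrp1, Olfml2a, Car3, Serpinb5, Samd5 and Epyc with sex as a covariate. Only Ccr4 of the 23 passed with the mesenchyme score as a covariate, as in limma on log2(TPM + 1), which did not measure Mrc1.

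**Figure D2:**
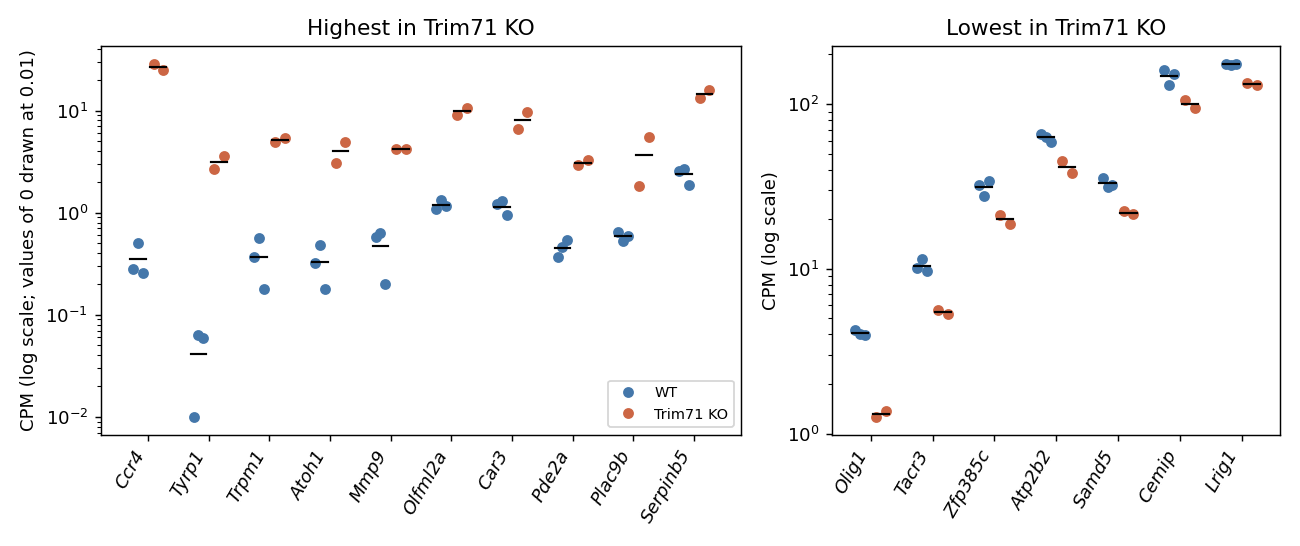
CPM per library on a log scale for the 10 genes with the highest and the 7 with the lowest log2 fold change among those past the threshold that the naming rule takes (mean of at least 1 CPM, no predicted or clone name), with 1 point per library (WT blue, Trim71 KO orange) and a bar at each group's mean. Ccr4 has a mean of 26.8 CPM in KO and 0.348 CPM in WT, and Olig1 1.32 CPM in KO and 4.10 CPM in WT.

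Ccr4 (chromosome 9, 114490316 to 114504916, minus strand) starts 2217 bases past the end of Trim71 on the same strand. Its counts were 13, 24 and 13 in WT against 1322 and 1205 in KO (edgeR adjusted p = 4.23e-05). Its other neighbours, named after their values were seen, did not pass. C130032M10Rik, which lies inside Trim71 on the plus strand, had a log2 fold change of 1.178 (edgeR adjusted p = 0.501), and Susd5, at a distance of 408405 bases, had 0.865 (edgeR adjusted p = 0.722). Crtap had 0.41 (edgeR adjusted p = 0.168), Glb1 had 0.17, and Cnot10, beyond the other end of Trim71, had 0.00. Of the 19 tested genes within 1 Mb of Trim71, none but Ccr4 was called.

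**Figure D3:**
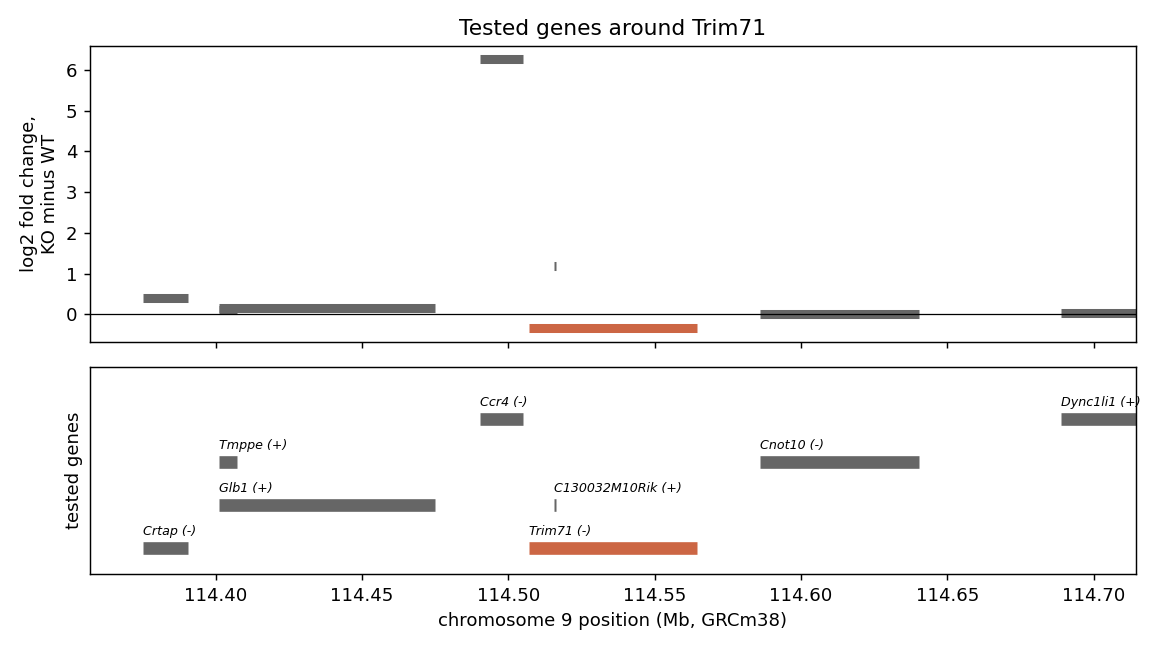
Tested genes around Trim71 on chromosome 9 (position in Mb, GRCm38); the upper panel gives each gene's log2 fold change, KO minus WT, and the lower panel its extent and strand, with Trim71 in orange. Ccr4 stands at 6.26 and C130032M10Rik at 1.178, and Crtap, Glb1 and Cnot10 lie between 0.00 and 0.41.

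The hair cell, supporting cell and tectorial lists passed upward in camera, but none of them did with an estimated correlation, and few of their members passed. Of 30 tested hair cell genes, 2 rose, Atoh1 and Cdh23, the latter a cadherin of the hair bundle's tip links with a log2 fold change of 1.72 ± 0.20 (SE). Adjusted over the list alone, 4 were higher and 1 lower. Myo6, a myosin of hair cells, had 0.35 ± 0.06 and did not pass over all genes (edgeR adjusted p = 0.0586). The list passed in camera (adjusted p = 0.000125), with adjusted p = 0.413 with an estimated correlation and 0.231 in fry, and the camera adjusted p was 0.0811 without KO replicate 4. Without KO replicate 6 the log2 fold change of Cdh23 was 1.494 (edgeR adjusted p = 0.105), and with the effective-length offset it was 1.138 (edgeR adjusted p = 0.279).

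Of 27 tested supporting cell genes, 2 rose, Epyc and Trpm1, and 8 were higher adjusted over the list alone. Epyc, a proteoglycan, went from 13.1 CPM ± 1.95 (SD, n = 3) to 37.2 CPM ± 4.56 (SD, n = 2). Bace2 and Lgr6, a protease and a Wnt-related receptor, had log2 fold changes of 1.92 ± 0.37 and 1.16 ± 0.23 (SE) and did not pass over all genes. Camera called the supporting cell list (adjusted p = 3.51e-14), with adjusted p = 0.0944 with an estimated correlation. Fry gave the supporting cell list an adjusted p of 0.0155.

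Of 10 tested genes of the tectorial and otolithic matrix, Tecta rose. This main protein of the tectorial membrane went from 1338 CPM ± 41.0 (SD, n = 3) to 1987 CPM ± 7.89 (SD, n = 2). Its call was lost in edgeR without WT replicate 1, KO replicate 4 or KO replicate 6, with log2 fold changes of 0.552, 0.581 and 0.566 and an adjusted p of up to 0.269. Tectb and Col11a2 had log2 fold changes of 0.74 ± 0.16 and 0.87 ± 0.17 (SE), and Otol1, an otoconial protein, had -0.34 ± 0.09; none of these passed over all genes. Adjusted over the list alone, 4 were higher and 1 lower. As a group these genes passed in camera (adjusted p = 3.76e-05), with adjusted p = 0.373 with an estimated correlation and 0.168 in fry.

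None of the 19 prosensory genes passed, and the list did not pass in camera (adjusted p = 0.233), with adjusted p = 0.834 with an estimated correlation. It passed downward in camera without WT replicate 2 (adjusted p = 0.0012) and with sex as a covariate (adjusted p = 0.0115), and upward with the mesenchyme score as a covariate (adjusted p = 0.0301), so these libraries do not settle its direction. Lfng and Tbx1 had log2 fold changes of -0.32 and -0.31.

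Markers of several other cell types had positive median log2 fold changes as well. The 17 periotic mesenchyme genes had a median log2 fold change of 0.85, and none passed over all genes, while 4 were higher adjusted over the list alone. Col1a2, a fibrillar collagen, was at 42.9 CPM ± 10.2 (SD, n = 3) in WT and 140 CPM ± 23.4 (SD, n = 2) in KO. Summed over the list, the libraries held 735, 851 and 874 CPM in WT and 1144 and 1353 CPM in KO. Mesenchyme genes passed as a group in camera (adjusted p = 2.99e-14), with adjusted p = 0.404 with an estimated correlation.

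Of 11 melanocyte genes, Tyrp1 and Trpm1 rose, and 9 were higher adjusted over the list alone. Gpnmb and Tyr had log2 fold changes of 1.69 and 1.54, and the median of the list was 1.72. Its summed values were 46.2, 76.4 and 61.4 CPM in WT and 143 and 155 CPM in KO. Melanocyte genes passed as a group in camera (adjusted p = 1.09e-37), with adjusted p = 0.152 with an estimated correlation.

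The 12 endothelial genes had a median of 1.53 and none passed over all genes. Their summed values were 20.01, 54.6 and 17.1 CPM in WT and 70.8 and 83.5 CPM in KO, so WT replicate 2 lay nearest to the KO libraries. Emcn and Pecam1, endothelial surface proteins, had log2 fold changes of 1.83 and 0.91. The list passed in camera (adjusted p = 2.7e-10), with adjusted p = 0.412 with an estimated correlation and a camera adjusted p of 0.0522 with the mesenchyme score as a covariate. Of 13 macrophage genes, Mrc1, a mannose receptor, rose with a log2 fold change of 1.79, and C1qb had 1.76 without passing. Mrc1 lost its call in edgeR without WT replicate 1, KO replicate 4 or KO replicate 6, with log2 fold changes of 1.736, 1.572 and 1.988 and an adjusted p of up to 0.156. That list passed in camera (adjusted p = 7.29e-11), with adjusted p = 0.373 with an estimated correlation.

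**Figure D4:**
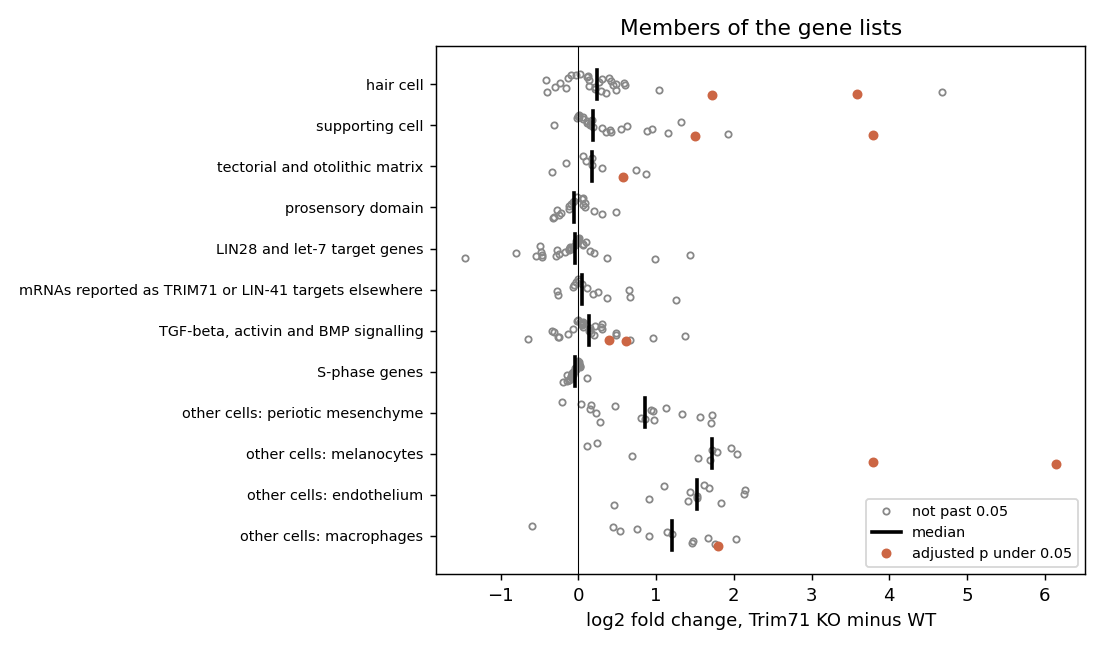
Log2 fold change, Trim71 KO minus WT, of each tested member of 12 gene lists; filled orange points passed the threshold in edgeR, open grey points did not, and black bars mark list medians. The medians of the mesenchyme, melanocyte, endothelium and macrophage lists are 0.85, 1.72, 1.53 and 1.204, and that of the hair cell list is 0.24.

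Of 35 genes of the LIN28 and let-7 list none passed over all genes, and 2 were higher and 2 lower adjusted over the list alone. The median of the list was -0.047, with single members further from 0. Myc and Ccnd2, which promote cell division, had log2 fold changes of 0.98 and 0.37, and Sall4 and Arid3b had -1.45 and -0.46. The list passed downward in camera (adjusted p = 0.00924), with adjusted p = 0.542 with an estimated correlation. Its camera adjusted p was 0.375 without WT replicate 3, 0.117 without KO replicate 6 and 0.532 with the mesenchyme score as a covariate.

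None of the 29 S-phase genes passed, and their median was -0.05. Cdt1, which licenses replication origins, had a log2 fold change of -0.15 and did not pass. The list passed downward in camera (adjusted p = 0.0248), with adjusted p = 0.558 with an estimated correlation. Its camera adjusted p was 0.0639 without WT replicate 2, 0.208 without WT replicate 3, 0.733 without KO replicate 4, 0.0811 with the effective-length offset and 0.381 with sex as a covariate.

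None of 15 mRNAs reported elsewhere as targets of TRIM71 or its worm counterpart passed over all genes. Nab2, a corepressor, Zfp36l2, an mRNA decay factor, and Inhba had log2 fold changes of 1.26, 0.37 and 0.66, and Cdkn1a had -0.27. Adjusted over the list alone, 3 were higher and 1 lower. The list passed in camera (adjusted p = 0.0478), with adjusted p = 0.412 with an estimated correlation, and fry gave an adjusted p of 0.0171. This call was lost in every camera alternative run: without any 1 library, with another scaling, with the effective-length offset and with each of the 3 covariates its camera adjusted p lay between 0.0519 and 0.153.

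Of 31 genes of TGF-beta, activin and BMP signalling, 2 rose, Fstl1, a secreted follistatin-like protein, and Ltbp3, which binds latent TGF-beta. Their log2 fold changes were 0.61 ± 0.10 and 0.39 ± 0.07 (SE). Both lost their calls in edgeR without WT replicate 1 and without KO replicate 6, and Ltbp3 also without WT replicate 3 or KO replicate 4, with adjusted p of up to 0.34 and 0.411 at log2 fold changes of 0.483 and 0.35. Msx1, a transcription factor downstream of BMP signals, had -0.65 ± 0.16 and did not pass. Adjusted over the list alone, 3 were higher and 1 lower. The list passed in camera (adjusted p = 0.0248), with adjusted p = 0.533 with an estimated correlation. Its camera adjusted p was 0.179 without WT replicate 2, 0.518 without KO replicate 6, 0.0695 with the effective-length offset and 0.293 with sex as a covariate.

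In all, 16 of 31 lists passed in camera, 14 upward and 2 downward. The other upward lists were Wnt signalling, early response genes, hypoxia and glycolysis, cartilage and erythroid cells. With an estimated correlation their adjusted p were 0.413, 0.533, 0.478, 0.412 and 0.404. Wnt signalling lost its camera call without WT replicate 2 (adjusted p = 0.0808), without KO replicate 6 (0.122) and with the mesenchyme score as a covariate (0.102). Early response genes lost theirs without KO replicate 6 (adjusted p = 0.786) and turned downward with that score (0.275). Cartilage, of the fits without 1 library, passed only in that without KO replicate 4, with adjusted p of up to 0.552 in the others, 0.0899 with the protein-coding share as a covariate and 0.63 with that score.

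With an estimated correlation none of the 31 lists passed in camera, where 4 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0944. Fry called 2 lists. Among the lists that did not pass, those of Notch, FGF and Hedgehog signalling had camera adjusted p of 0.836, 0.933 and 0.162, and the G2 and M-phase genes 0.789. In edgeR 1 member of the FGF list and 1 of the Hedgehog list were called higher over all genes. Hedgehog signalling passed downward without WT replicate 2 (camera adjusted p = 0.013) and with sex as a covariate (0.0325), and the G2 and M-phase genes passed downward with the mesenchyme score as a covariate (0.00994).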

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

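The tests of these transcripts were chosen after the data were examined. Among the 1761 transcripts tied to no gene, 730 could be tested together with the genes, and 2 passed the threshold in edgeR, both higher in the KO libraries. Of the 730, 23 had an unadjusted p under 0.05 in edgeR, fewer than chance alone would give. Of 18862 tested genes 104 were called, so 2 of 730 is not a larger share. Both are single transcripts, and the edgeR test of transcripts tied to a gene called 0 of 66162. That test called no transcript of Ccr4 either, so its 0 calls do not bear on these 2. ENSMUST00000201922.3 had 0 counts in each WT library against 28 and 39 in the KO libraries (edgeR adjusted p = 0.0321). Its mean of 0.706 CPM in KO was at least 34.0-fold higher than the limit of 3 counts over the WT group, while its fitted log2 fold change of 8.08 depends on the prior count. ENSMUST00000201188.3 had 18, 29 and 35 counts in WT against 132 and 147 in KO, a log2 fold change of 2.38 (edgeR adjusted p = 0.0276). What these transcripts encode was not analysed here.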

How the results depend on the processing

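No paired analysis was possible because the labels give no litter or pairing for each library, so an effect of litter could not be tested. In every gene-level fit that measured them, the 104 called genes kept their direction. Both KO libraries lay on one side of the WT libraries for each, so leaving out 1 library could hardly change it. The number of called genes moved. It was 100 with another scaling and 77 with a mean of at least 1 CPM. It was 244 without the low-count filter, 387 with DESeq2, 65 with limma-voom, 34 with the effective-length offset, 6 with limma on log2(TPM + 1) and 45 with the fit that is not robust. Leaving out 1 library gave between 32 and 374, the lowest without KO replicate 6 and the highest without WT replicate 2. Testing transcripts gave 0 in edgeR and 0 in limma-voom, of 66162, with 1899 and 2161 at an unadjusted p under 0.05. Both of these counts are fewer than chance alone would give. The smallest adjusted p of transcripts in edgeR was 0.132, although 1 Ccr4 transcript had 10, 24 and 12 counts in WT against 1180 and 1094 in KO. These transcript tests thus missed a clear change, and their 0 calls do not show that transcripts were unchanged. Among settings chosen after seeing the data, the count was 47 with sex, 238 with the protein-coding share and 9 with the mesenchyme score as a covariate, and 101 without members of the other-cell lists. Trim71 had negative log2 fold changes throughout and passed in none. Of 31 lists, 0 passed with an estimated correlation and 2 with fry, and leaving out 1 library gave between 10 and 16. With the mesenchyme score as a covariate, Hmga2, Sox2, Fgf20 and Ramp2 changed sign, to 0.029, 0.10, 0.11 and -0.10, and without 1 library Fgf20 ranged from -0.22 to 0.004, the latter without WT replicate 3; none of them passed before or after. The cause of these shifts was not tested.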

Other observations

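Other genes past the threshold, chosen after their values were seen, had large and even differences. Emp1, a membrane protein of epithelia, went from 12.4 CPM ± 1.16 (SD, n = 3) in WT to 45.1 CPM ± 5.51 (SD, n = 2) in KO. Enpep, an aminopeptidase, went from 4.43 to 23.9 CPM, and Slc1a2, a glutamate transporter, from 6.81 to 30.3 CPM. Hoxd8 had 0, 1 and 0 counts in WT against 19 and 22 in KO. The pseudogenes Gm10259 and Gm18551 had 0 counts in both KO libraries against 96, 173 and 161 and 43, 36 and 56 in WT, at least 93.5-fold and 29.3-fold lower at 3 counts over the KO group, and such copies share reads with related genes. Tyrp1 had 3.29 counts per 100 counts of Dct, Pmel and Tyr in KO and 0.15 in WT, a ratio of 21.5 (95% exact Poisson interval 9.8 to 59.0, counting error only).

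All tests in the paragraphs that follow were chosen after the results they address were seen. Ccr4 had the smallest p of all genes and lies beside Trim71. T cells, which carry this receptor, are argued against as its source, since 6 T-cell transcripts summed to 15.2 CPM in KO and 16.4 CPM in WT, a difference of -1.18 CPM, where Ccr4 differed by 26.4 CPM. A candidate explanation is a local effect of the altered locus, since Ccr4 lies 2217 bases away on the same strand and no other gene within 1 Mb was called. A sequence variant linked to the altered allele stays open, because of 77 tested genes within 5 Mb only 1 other, Tgfbr2, was called. An effect of lost TRIM71 protein on Ccr4 was not tested.

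Most called genes were higher in the KO libraries, where markers of mesenchyme, melanocytes, endothelium, macrophages and erythroid cells were higher too. The 9 tested erythroid genes all had positive log2 fold changes, with a median of 0.99. Of these cell types only mesenchyme was tested as a covariate. More mesenchyme in the KO libraries cannot be told apart from genotype. With its score as a covariate 4 of the 95 higher genes were still called, as standard errors grew 1.86 times. The 307 higher genes called without WT replicate 2 lay in it a median share of 0.27 of the way to the KO libraries. Their quartiles, 0.08 and 0.5, enclosed those of mesenchyme markers, 0.32 and 0.46, with a median of 0.38. These markers were 12 of the 17 mesenchyme genes, all with a mean of at least 0.5 CPM. They were kept for a KO mean over 1.3 times that of WT replicates 1 and 3. Endothelium markers lay at a median of 0.65. With the mesenchyme score as a covariate all 95 kept positive log2 fold changes, with a median of 0.74 after and 0.87 before. The median of the mesenchyme list went from 0.85 to 0.17, a fall set in advance because the score is made from that list. The 95 were called for higher values in these same libraries. This contrast therefore does not decide whether mesenchyme is the whole cause, and most of the calls were lost. Sex stays open as well. WT replicate 1 is the WT library with Y-linked transcripts, so with sex as a covariate genotype rests on it against the KO libraries. In that fit 23 of the 95 were still called, with a median of 0.94 and standard errors 1.64 times as large. Genes called without WT replicate 1 lay in it a median share of 0.00 of the way to the KO libraries, against 1.07 for Y-linked genes. That share goes against sex, but it rests on the same 1 library and is not separate evidence. The 10 splits of 5 libraries into 3 and 2 are too few for a share under 0.05; the real split called 104 genes, more than in the other splits, of which the highest called 24, so 1 split reached that count.

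Atoh1, Cdh23, Epyc and Tecta, the called genes of the hair cell, supporting cell and tectorial lists that are in no list of other cells, were higher in KO. More mesenchyme stays open for them: their median log2 fold change was 1.61 before and 1.23 with the mesenchyme score as a covariate, and none of the 4 was still called in edgeR as standard errors grew 1.79 times. In WT replicate 2, 8 members of these lists called without it lay a median share of 0.08 of the way to the KO libraries. The mesenchyme markers lay at 0.38. These were 12 of the 17 mesenchyme genes, kept for a KO mean over 1.3 times that of WT replicates 1 and 3. Summed over all 17, WT replicate 2 held 851 CPM, against 735 and 874 CPM in WT replicates 1 and 3. In the mesenchyme score it stood at 4.164, above 3.352 and 3.903. Its place thus depends on the summary, and 1 library does not decide the question. Vestibular tissue, whose hair cells form early, may also have entered the dissection and cannot be told apart. Its markers split, with a median log2 fold change of 0.34. Hmx3 at 0.79 passed over all genes (edgeR adjusted p = 0.0495). Hmx2 at 0.94 passed only over the markers alone (edgeR adjusted p = 0.0125). Dlx5 at -0.12 and Dlx6 at -0.15 did not pass over the markers alone (edgeR adjusted p = 0.729 for both). All of these markers are also in the list of nonsensory cochlear epithelium. Earlier differentiation in the KO epithelium could give the same values and was not tested separately from more mesenchyme or vestibular tissue.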
